A study of Mus musculus with 8 samples.

How the data were processed

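The series measured messenger RNA in mouse blood stem and progenitor cells on 8 Affymetrix mouse expression arrays, 2 per group in 4 groups. Per the labels' protocols, equal numbers of CD45.2+ marrow cells carrying the BCR-ABL and SCL-tTA transgenes and of CD45.1+ marrow cells were given to CD45.1+ hosts, and control chimeras were made without the BCR-ABL transgene. BCR-ABL is the fusion kinase of chronic myeloid leukaemia, and the SCL-tTA driver switches it on in stem and progenitor cells once tetracycline is withdrawn from the drinking water. Per the series' design text, CD45.1+ cells, which do not carry the transgene, were sorted into Trizol 4 weeks after withdrawal, and RNA was amplified with the Nugen Ovation Pico system. The labels' labelling protocol instead describes biotinylated cRNA from total RNA by the standard Affymetrix method, so the amplification used is not settled here. HSC stands for the CD150+ CD48- fraction of KSL cells (lineage negative, Kit+, Sca-1+), and KSL for the whole KSL gate. Groups were taken from the disease state and cell type labels. The free-text descriptions, which speak of embryos, were not used, and the titles of the KSL samples of leukemic mice carry both wordings, so their disease state label was used. The labels do not say that replicates came from separate animals, and p-values then measure the spread between these samples.

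The authors deposited 1 table of log2 values with 45101 probe sets. RMA (background correction, quantile normalization and median polish) is named in the submitters' processing notes, without a version, and further steps are not given in the sources used here. The deposited values had a floor at exactly 10.0 on the linear scale (3.32 in log2), which held between 14.9% and 15.8% of probe sets on each array, and array medians lay between 5.74 and 5.86. Values at the floor have no order, and a fold change against a group with both arrays at the floor is given as a lower bound. The 8 columns matched the 8 samples and 0 other columns of samples were left unused.

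Probe sets were named through the platform annotation supplied with the table: 34945 had 1 gene symbol, 932 had several, 9160 had none, and 64 were controls. Of those with 1 symbol, 34754 were found by their gene identifier in the RefSeq table of assembly GRCm38.p6, which served for names only, and 0 symbols had to be updated. The probe set with the highest mean over the 8 arrays represented each gene, which gave 18193 genes, 9010 of them with more than 1 probe set. No filter on dim genes was applied, and 1290 genes lay at the floor on all 8 arrays. Log2 values were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 1 mean per group over all 8 arrays, 4 residual degrees of freedom, prior degrees of freedom 0.67), with two-sided tests and Benjamini-Hochberg adjustment over all genes. A gene passed at an adjusted p under 0.05. The 5 comparisons were leukemic against normal in HSC, the same in KSL, the average of both, the interaction (the HSC difference minus the KSL difference), and HSC against KSL in normal mice. Errors given after a log2 fold change are standard errors of the fit with n = 2 arrays per group, and the number of arrays limits the precision. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

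The design, the comparisons, the alternatives and 27 gene lists from textbook knowledge (543 entries, 502 of them measured) were fixed before the data were examined. Lists were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the 27 lists of a comparison, with camera at an estimated correlation and fry (a self-contained rotation test) as alternatives. Of the 57 list calls in the 5 comparisons, 6 held with an estimated correlation and 36 with fry. All 6 are in HSC against KSL of normal mice. Genes were named by a fixed rule: up to 10 higher and 10 lower per comparison with the largest fold change among those that passed and whose arrays did not overlap, leaving out unnamed genes, receptor families of smell, small RNAs and antigen receptor segments. For each called list, and for 5 lists of special interest, the rule adds up to 4 passing members or the 2 with the smallest p, and in every comparison the genes of the sort gates. Where fewer than 10 genes passed, the 5 with the smallest p in each direction were added as values. Other list members are named only with their p adjusted over the list alone, and were chosen after their values were seen.

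The gene-wise test was checked on simulated data for 18193 genes with 100 genes changed by 1 and 100 by 2 log2 units. With noise drawn from each gene's own 2-replicate spread, the HSC comparison recovered 36% and 62% of changed genes with 304 false among 402 calls, and the KSL comparison 23% and 58% with 30 false among 111. A second noise model, chosen after that result, used moderated gene spreads scaled to each group. It recovered 20% and 49% in HSC with 40 false among 109 calls, and 4% and 40% in KSL with 1 false among 45.

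Alternatives fixed in advance were quantile normalization or cyclic loess on the deposited values, a shift to a common median, a filter on the lowest 40% of genes, the mean of probe sets or every probe set, an intensity trend with robust moderation, array weights, the replicate number as a block, only the compared groups in the fit, leaving out each of the 8 arrays, an adjusted p of 0.1, and a minimum log2 fold change of 1. Alternatives chosen after seeing the data left out genes at the floor on all or on any array, added a term for 2 arrays with a male pattern of sex-linked genes, or left out those 2 arrays.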

Results

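Gene expression was profiled in non-transformed CD45.1+ stem and progenitor cells from the marrow of leukemic and of normal chimeric mice. The 4 groups, with 2 arrays each, were HSC of normal mice, HSC of leukemic mice, KSL of normal mice and KSL of leukemic mice. Replicate arrays correlated with r = 0.965 in HSC of normal mice, 0.958 in HSC of leukemic mice, 0.988 in KSL of normal mice and 0.994 in KSL of leukemic mice, across genes, which are not independent replicates. The median standard deviation between replicates was 0.23 and 0.24 log2 units in the HSC groups and 0.13 and 0.11 in the KSL groups, so the HSC arrays were the noisier ones. Replicate 1 of both normal groups carried a male pattern of sex-linked genes. Xist, which is transcribed from the inactive X chromosome, was at 5.79 and 3.67 there against 11.6 to 12.0 on the other 6 arrays, and Eif2s3y, a Y-linked translation factor, was at 9.23 and 9.35. The other 6 arrays had a female level of Xist, but their Y-linked signal was not uniform. Kdm5d, also Y-linked, was at 5.69 on HSC normal 2, 5.94 on HSC leukemic 2 and 5.86 on KSL normal 2. Eif2s3y was at 6.01, 5.72 and 6.24 on these arrays. On HSC leukemic 1 and both KSL leukemic arrays Kdm5d was at 4.68 or less and Eif2s3y at 5.51 or less. Leaving out the male arrays thus does not leave arrays with equal Y-linked signal, and the source of that signal was not tested.

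The first comparison asked how HSC that had shared the marrow with BCR-ABL-expressing cells differed from HSC of control chimeras. Genes of the granulocyte-monocyte progenitor programme were higher as a group, with a median log2 fold change of 1.06 and 16 of 18 measured members higher (camera adjusted p = 4.00e-07, and adjusted p = 0.207 with an estimated correlation). Adjusted over the list alone, 7 members rose, while limma passed 0 of 18 when adjusted over all genes, with 9 at an unadjusted p under 0.05. Ctsg, which encodes the neutrophil granule protease cathepsin G, rose by 2.74 ± 0.25 (adjusted p = 0.00302 over the list alone and 0.0819 over all genes). Hp, the haemoglobin-binding plasma protein haptoglobin, rose by 2.27 ± 0.28 (0.00584 and 0.105). Myeloperoxidase (Mpo) rose by 2.58, Ly86 by 2.47, the monocyte transcription factor gene Irf8 by 1.58, the shared beta chain of the GM-CSF receptor (Csf2rb) by 1.43 and Ms4a3 by 1.23, each adjusted over the list alone. Ctsg reached a mean of 9.01 in HSC of leukemic mice against 6.27 in HSC and 12.76 in KSL of normal mice. The list kept its call whichever array was left out and in every camera setting with the preset correlation.

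Control probes that read RNA quality differed between the HSC groups too, beside each of the 5 lists called there, a comparison chosen after results were seen. The 3 prime minus 5 prime difference was 0.78 and 0.83 in HSC of normal mice against 1.19 and 1.03 in HSC of leukemic mice for Gapdh, -2.04 and -1.74 against -0.36 and -0.75 for Tfrc, and -0.37 and -0.38 against -0.42 and -0.50 for Actb. Actb thus moved the other way from Gapdh and Tfrc. The spike-in BioB, which reads hybridisation and not RNA quality, was at 10.24 and 10.14 in HSC of leukemic mice, above both HSC arrays of normal mice. The spike-in BioC overlapped, at 12.36 and 12.14 in HSC of leukemic mice against 12.19 and 11.97 in HSC of normal mice.

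Markers of mature neutrophils and monocytes were also higher in HSC of leukemic mice, with a median of 1.82 and 15 of 17 members higher (camera adjusted p = 0.0011, and adjusted p = 0.498 with an estimated correlation). Adjusted over the list alone, 1 member rose, Wfdc21, by 3.28 ± 0.54 (adjusted p = 0.0389 over the list alone and 0.141 over all genes). Limma passed 0 of 17 members over all genes, with 5 at an unadjusted p under 0.05. The antimicrobial siderophore-binding protein gene Lcn2 had a log2 fold change of 3.88, the calgranulin gene S100a8 2.86, and the monocyte chemokine receptor gene Ccr2 2.53 ± 0.56 (adjusted p = 0.198). None of them passed over the list alone. The 2 arrays of HSC of normal mice lay far apart for Lcn2 (-0.53 and -3.85 from the gene mean) and S100a8 (0.48 and -3.38). This list depended on single arrays. Its median deviation from the gene means was -0.02 on array 1 and -1.24 on array 2 of HSC of normal mice, against 0.96 and 0.43 on the leukemic arrays. Without HSC normal 2 the median was 0.48 (adjusted p = 0.0938), and without HSC leukemic 1 it was 1.00 (adjusted p = 0.093).

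Genes of long-term HSC identity were lower as a group in HSC of leukemic mice, with a median of -0.40 and 16 of 23 members lower (camera adjusted p = 0.0438). Adjusted p was 0.424 with an estimated correlation. Procr, the endothelial protein C receptor used to mark HSC, had a log2 fold change of -1.25 ± 0.29 (adjusted p = 0.209) and Fgd5, another HSC marker, of -1.71 ± 0.44 (adjusted p = 0.23). Limma passed 0 of 23 members over all genes and 0 adjusted over the list alone, with 5 at an unadjusted p under 0.05. The call was lost without HSC normal 1 (adjusted p = 0.222), HSC normal 2 (0.0755), HSC leukemic 2 (0.356) or either KSL leukemic array (0.0532). It was also lost with a term for the male arrays (0.0633), without them (0.135) and without the lowest 40% of genes (0.0581). The genes of the sort gates did not pass, with Slamf1 (CD150) at -0.78 ± 0.51 (adjusted p = 0.595) and Cd48 at 0.02 ± 0.82 (adjusted p = 1). Kit was at 0.11 ± 0.37 (0.992) and Ptprc (CD45) at -0.00 ± 0.21 (1). Ly6a, the gene of Sca-1, has no probe set with a single symbol and was not analysed here.

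Genes of IL-6 and JAK-STAT3 signalling had a median of 0.28 in HSC, with 18 of 27 members higher (camera adjusted p = 0.0442, and adjusted p = 0.424 with an estimated correlation). Of these, 4 rose and 1 fell when adjusted over the list alone, and over all genes limma passed 0, with 13 at an unadjusted p under 0.05. Socs3, the feedback inhibitor of STAT3 signalling, rose by 1.70 ± 0.16 (adjusted p = 0.00276 over the list alone and 0.0819 over all genes), and Lifr by 1.15 ± 0.11 (0.00276 and 0.0866). Over the list alone Bcl3 also rose, by 1.53, and Pim2, by 0.92, while the phosphatase gene Ptpn2 fell by 0.70. The list lost its call without HSC normal 1 (adjusted p = 0.222), HSC normal 2 (0.0938), HSC leukemic 1 (0.13), either KSL normal array (0.0506) or either KSL leukemic array (0.054). The male term (0.193), leaving out the male arrays (0.305), leaving out genes at the floor on any array (0.0618) and a fit of the HSC arrays alone (0.0793) ended it as well.

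B lineage genes had a median of 0.19 with 9 of 13 members higher (camera adjusted p = 0.0442, and adjusted p = 0.424 with an estimated correlation). Adjusted over the list alone, Cd79b, the B cell receptor signalling chain, rose by 1.24 ± 0.18 (0.0182; 0.133 over all genes) and the surrogate light chain gene Igll1 by 2.47 ± 0.45 (0.0221; 0.157). Limma passed 0 of 13 over all genes, with 5 at an unadjusted p under 0.05. The call was lost without HSC normal 1 (median 0.30, adjusted p = 0.222), HSC normal 2 (0.47, 0.167), HSC leukemic 1 (0.05, 0.166), HSC leukemic 2 (0.28, 0.131) or either KSL leukemic array (0.054). It was lost with the male term (0.128), without the male arrays (0.141), with array weights (0.0646), after cyclic loess (0.0555), and without genes at the floor on any array (0.0766) or the lowest 40% of genes (0.87, 0.0748).

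The other 22 lists were not called in HSC. Interferon response genes had a median of -0.09 (camera adjusted p = 0.235), with Irf9 at -1.33 ± 0.27 (adjusted p = 0.179) and Ddx58 at -0.68 ± 0.20 (0.266). Proliferation genes had a median of 0.01 (0.709), although the mitotic kinesin gene Kif11 rose by 1.06 ± 0.07 (adjusted p = 0.0458). Immediate-early genes had a median of 0.09, a mean of -0.11 and camera's direction down (0.709), and multipotent progenitor genes a median of -0.04 and a mean of 0.09 (0.72). Among markers of other cells, macrophages had a median of -0.38 (0.163), mast cells and their relatives 0.36 (0.163) and megakaryocytes 0.51 (0.346). Erythroid cells had a median of -0.23 (0.309), T and NK cells 0.23 (0.283) and stromal and endothelial cells -0.09 with a mean of 0.02 (0.709). Leukaemic stem cell genes had a median of -0.14 (0.163), glycolysis -0.13 (0.163), heat shock and unfolded protein response -0.11 (0.068) and p53 response 0.30 (0.235). Homing had a median of 0.11 (0.439), TGF-beta 0.01 (0.954), antigen presentation -0.02 (0.709), quiescence -0.09 (0.954) and oxidative phosphorylation -0.03 (0.519). Ribosomal proteins had a median of 0.02 and a mean of -0.04 (0.346), TNF and NF-kB genes a median of -0.03 and a mean of 0.04 (0.892), and the 4 sex-linked genes a median of -2.28 (0.346).

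**Figure D1:**
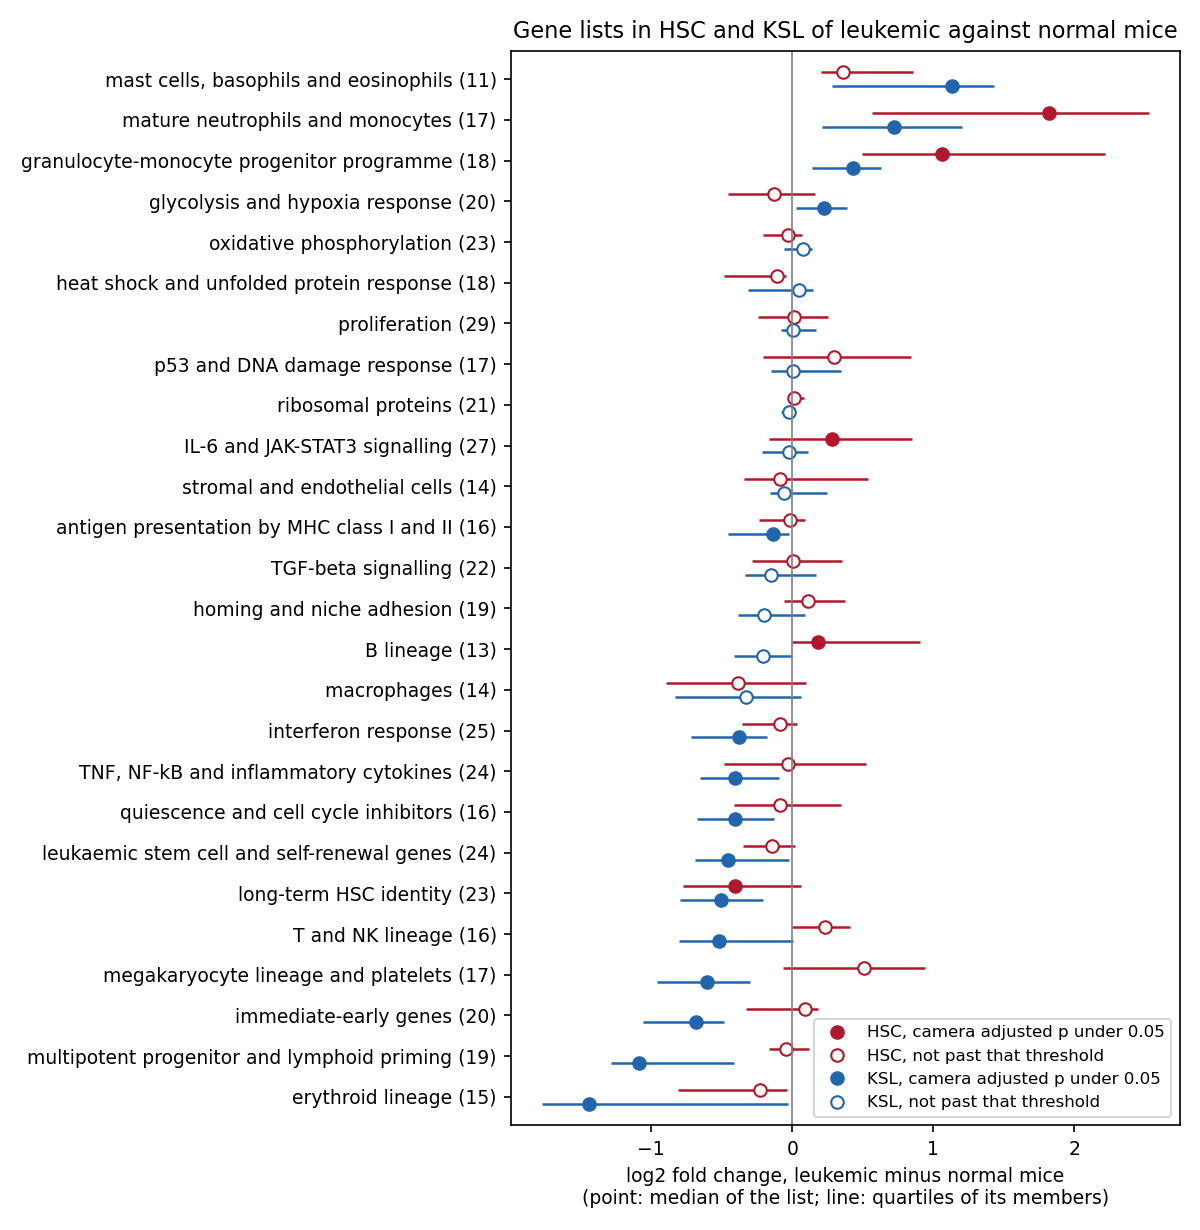
Median log2 fold change, leukemic minus normal mice, of 26 gene lists in HSC (red) and KSL (blue), with lines for the quartiles of the members and filled points where camera's adjusted p was under 0.05. The granulocyte-monocyte progenitor list lay at 1.06 in HSC and 0.43 in KSL, and the immediate-early list at 0.09 and -0.68.

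Gene by gene, 11 genes rose and 7 fell in HSC of leukemic mice out of 18193 tested, with 2505 at an unadjusted p under 0.05. Chance gives 909.65 only if all groups vary alike. The fit pools the noisier HSC arrays with the KSL arrays, so p-values in HSC tend to be too small. In the simulations 304 of 402 and 40 of 109 calls in HSC were false, each more than the 18 calls made here. The simulated noise thus does not match that of these data. An adjusted p under 0.05 may not hold false calls to that share, and the share of false calls among the 18 is not known. Il1r1, the signalling receptor for interleukin-1, rose by 1.95 ± 0.08 (adjusted p = 0.0219), and the AP-1 family member Fosl2 by 1.47 ± 0.06 (0.0219). The ubiquitin ligase gene Rnf217 rose by 1.74 ± 0.11 and the phospholipid flippase gene Atp8b4 by 1.56 ± 0.09. The acyltransferase gene Lpgat1 rose by 1.38 ± 0.09, Cdc42ep2 by 0.71 ± 0.04 and Cirbp, which encodes a cold-inducible RNA-binding protein, by 0.72 ± 0.04. The collagenase gene Mmp13 was at least 2.99-fold and Scara3 at least 2.73-fold higher, both at the floor in HSC of normal mice. The secreted growth factor gene Bmp4 was at least 4.58-fold lower and the transporter gene Slc16a12 at least 2.22-fold lower (adjusted p = 0.00488). The collagen gene Col4a5 was at least 1.35-fold lower, and all 3 were at the floor in HSC of leukemic mice. Slc16a12 was also at the floor in KSL of both groups. Its spread, and with it its adjusted p, is therefore set largely by the floor and does not measure variation between samples. Of the 18 calls, 5 had at least 1 array at the floor. The phosphatase gene Ptpn14 fell by 1.81 ± 0.11, the membrane-bound transcription factor gene Creb3 by 1.43 ± 0.10 and Uevld by 1.26 ± 0.07. The zinc finger repressor gene Trps1 was 2.84-fold lower (0.0219). Another probe set of the same gene gave 0.00 for Il1r1, 0.08 for Fosl2, -0.30 for Rnf217 and -0.85 for Lpgat1.

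These gene calls in HSC depended on the arrays in the fit. Shifting all arrays to a common median gave 16 higher and 4 lower (9 of the 18 among them), and array weights 0 higher and 2 lower. With only the 4 HSC arrays in the fit limma passed 0 genes (1459 at an unadjusted p under 0.05). Without KSL normal 1 or KSL normal 2, 1 gene passed, Ptpn14. Without KSL leukemic 1 or KSL leukemic 2, limma passed 0 genes (1962 at an unadjusted p under 0.05). With 1 HSC array left out, 127 genes passed without HSC normal 1 (12 of the 18 among them), 36 without HSC normal 2 (5), 257 without HSC leukemic 1 (18) and 235 without HSC leukemic 2 (18). In these fits the remaining array of that group was assumed to vary like the other groups. With a term for the male arrays limma passed 0 genes (2238 at an unadjusted p under 0.05), and without those arrays 0 (2740).

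The second comparison set KSL of leukemic against KSL of normal mice. Immediate-early genes, which are induced within minutes of a stimulus, were lower as a group, with a median log2 fold change of -0.68 and 19 of 20 members lower (camera adjusted p = 2.16e-14, and adjusted p = 0.069 with an estimated correlation). Of these, 11 fell when adjusted over the list alone. The MAP kinase phosphatase gene Dusp1 fell by 0.58 ± 0.04 (adjusted p = 0.00143 over the list alone and 0.0993 over all genes) and the AP-1 gene Jun by 0.79 ± 0.10 (0.00601 and 0.215). Over the list alone Fosb fell by 1.14, Fos by 0.73, the zinc finger gene Egr1 by 1.46 and the nuclear receptor gene Nr4a1 by 1.64. Genes of multipotent progenitors and lymphoid priming were lower for 19 of 19 members, with a median of -1.08 (camera adjusted p = 1.89e-11, and adjusted p = 0.0668 with an estimated correlation). Of these, 8 fell when adjusted over the list alone. Il12a, which encodes the p35 chain of interleukin-12, fell by 1.16 ± 0.06 (adjusted p = 0.0426 over all genes). Over the list alone the recombinase gene Rag1 fell by 1.17, the template-independent polymerase gene Dntt by 2.29, the interleukin-7 receptor gene Il7r by 1.25, Ccr9 by 0.95 and Cd34 by 0.75. Limma passed 0 of 20 immediate-early members over all genes, with 11 at an unadjusted p under 0.05, and 1 of 19 progenitor members. Both lists kept their calls whichever array was left out.

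Stem cell genes were lower as well in KSL of leukemic mice. Leukaemic stem cell and self-renewal genes had a median of -0.46 with 18 of 24 lower (camera adjusted p = 2.70e-05, and adjusted p = 0.0668 with an estimated correlation). Without KSL leukemic 2 the median was -0.28 (adjusted p = 0.000407). Adjusted over the list alone, 5 fell, among them the transcription factor genes Erg by 0.73 ± 0.09 (0.0107; 0.215 over all genes) and Meis1 by 1.15 ± 0.16 (0.0107; 0.215). Prdm16 fell by 1.87 ± 0.28 (0.0107; 0.225) and Mycn by 0.64. Long-term HSC identity genes had a median of -0.51 with 18 of 23 lower (camera adjusted p = 0.000673, and adjusted p = 0.0938 with an estimated correlation). There Meis1, Prdm16, Gata2, Trpc6 and Hlf fell and Ifitm1 rose, by 0.94, when adjusted over the list alone. Quiescence genes had a median of -0.41 with 13 of 16 lower (0.00015, and adjusted p = 0.082 with an estimated correlation) and -0.27 with the male term (0.00479). Of these, 4 fell over the list alone, among them the antiproliferative gene Tob1 by 1.53 ± 0.12 (0.00149; 0.0993 over all genes) and the cyclin-dependent kinase inhibitor gene Cdkn1b by 0.67 ± 0.10 (0.0141; 0.225). Limma passed 0 members of these lists over all genes, with 8, 7 and 6 at an unadjusted p under 0.05.

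Myeloid and mast cell genes were higher in KSL of leukemic mice. The mast cell, basophil and eosinophil list had a median of 1.13 with 10 of 11 higher (camera adjusted p = 0.000109, and adjusted p = 0.082 with an estimated correlation). The mast cell protease gene Cma1 rose by 2.95 ± 0.23 (adjusted p = 0.000944 over the list alone and 0.0993 over all genes), and Fcer1a, the alpha chain of the high-affinity IgE receptor, was at 2.38 ± 0.65 (0.0826 and 0.493). The granulocyte-monocyte progenitor list had a median of 0.43 with 14 of 18 higher (0.00144, and adjusted p = 0.121 with an estimated correlation). Hp was at 1.32 ± 0.28 (adjusted p = 0.342) and Irf8 at -0.89 ± 0.24 (0.475). Its median was 0.25 without KSL normal 1 (0.0348), 0.22 with the male term (0.0146) and 0.25 without both male arrays (0.0508). Mature neutrophil and monocyte markers had a median of 0.72 with 15 of 17 higher (0.0011, and adjusted p = 0.357 with an estimated correlation). The median was 0.24 without KSL normal 2 (0.0266), 1.11 without KSL leukemic 2 (0.00176) and 1.44 with the male term (1.52e-06). Wfdc21 was at 1.74 ± 0.54 (0.536) and Chil3 at 2.20 ± 0.78 (0.599). Glycolysis genes had a median of 0.23 with 15 of 20 higher (0.000892, and adjusted p = 0.082 with an estimated correlation). Lactate dehydrogenase A (Ldha) was at 0.31 ± 0.06 (0.341) and Bnip3 at 0.39 ± 0.10 (0.427). Limma passed 0 members of these 4 lists over all genes, with 6, 5, 3 and 8 at an unadjusted p under 0.05.

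Erythroid, megakaryocyte and interferon response genes were lower in KSL of leukemic mice. Megakaryocyte genes had a median of -0.61 with 15 of 17 lower (camera adjusted p = 0.000109, and adjusted p = 0.297 with an estimated correlation). The median was -0.34 without KSL normal 2 (0.024). Erythroid genes had a median of -1.44 with 11 of 15 lower (0.00131, and adjusted p = 0.351 with an estimated correlation). It was -0.77 without KSL normal 1 (0.0228) and -0.20 with the male term (0.0146). Carbonic anhydrase 2 (Car2) fell by 1.73 ± 0.23 over the list alone (0.0137; 0.215 over all genes), and the erythroid transcription factor gene Gata1 was at -1.44 ± 0.32 (0.0541; 0.358). Interferon response genes had a median of -0.38 with 21 of 25 lower (4.56e-05, and adjusted p = 0.0668 with an estimated correlation). Oasl2, of the oligoadenylate synthetase family, fell by 1.31 ± 0.10 over the list alone (0.0019; 0.0993), with Ddx58 at -0.83 ± 0.20 (0.0789; 0.401).

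Inflammatory, T and NK and antigen presentation genes were also lower in KSL of leukemic mice. TNF and NF-kB genes had a median of -0.40 with 18 of 24 lower (0.00372, and adjusted p = 0.134 with an estimated correlation), or -0.26 with the male term (0.0423). The interleukin-18 gene Il18 was at -2.23 ± 0.44 (0.287) and Nfkbie at -0.64 ± 0.17 (0.463). T and NK genes had a median of -0.52 with 10 of 16 lower (0.0167, and adjusted p = 0.13 with an estimated correlation). The median was -0.34 without KSL leukemic 1 (0.0256) and -0.23 without KSL normal 2, which ended the call (0.0887). It ended too without the lowest 40% of genes (median -0.07, 0.506) and in a fit of the KSL arrays alone (0.0732). The T cell receptor chain gene Cd3e fell by 1.35 ± 0.20 over the list alone (0.023; 0.225), and Gata3 was at -1.11 ± 0.24 (0.358). Antigen presentation genes had a median of -0.13 with 12 of 16 lower (0.0294, and adjusted p = 0.357 with an estimated correlation), or -0.21 with the male term (0.00225). They lost the call without KSL normal 2 (0.0887), KSL leukemic 1 (0.0728) or either HSC leukemic array (0.0719), after cyclic loess (0.0671) and without the lowest 40% of genes (0.101). The class II invariant chain gene Cd74 fell by 1.63 ± 0.27 over the list alone (0.0345; 0.228), and H2-Aa was at -0.91 ± 0.25 (0.481).

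Beside each of the 15 lists called in KSL, the 3 prime minus 5 prime difference of Tfrc was -1.28 and -1.58 in normal and -1.65 and -1.68 in leukemic mice, and that of Actb -0.48 and -0.48 against -0.53 and -0.53. That of Gapdh overlapped, at 0.89 and 0.74 against 0.73 and 0.75.

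The other 12 lists were not called in KSL. IL-6 and JAK-STAT3 genes had a median of -0.02 and a mean of 0.01 (camera adjusted p = 0.89). Socs3 rose by 1.12 ± 0.16 when adjusted over the list alone (0.0298; 0.215 over all genes), with Il4ra at 0.64 ± 0.22 (0.585). Proliferation genes had a median of 0.01 and a mean of -0.01 (0.754), with Ube2c at -0.31 ± 0.14 and Bub1 at 0.29 ± 0.13 (both 0.732). Heat shock and unfolded protein response genes had a median of 0.05, a mean of -0.64 and camera's direction down (0.148). Medians were -0.33 for macrophages (0.068), -0.21 for B lineage (0.148), -0.20 for homing (0.146), and -0.15 for TGF-beta (0.268). They were 0.08 for oxidative phosphorylation (0.0634), 0.01 for the p53 response (0.354), -0.02 for ribosomal proteins (0.89), -0.06 with a mean of 0.06 for stromal and endothelial cells (0.281) and -2.32 for the 4 sex-linked genes (0.222).

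**Figure D2:**
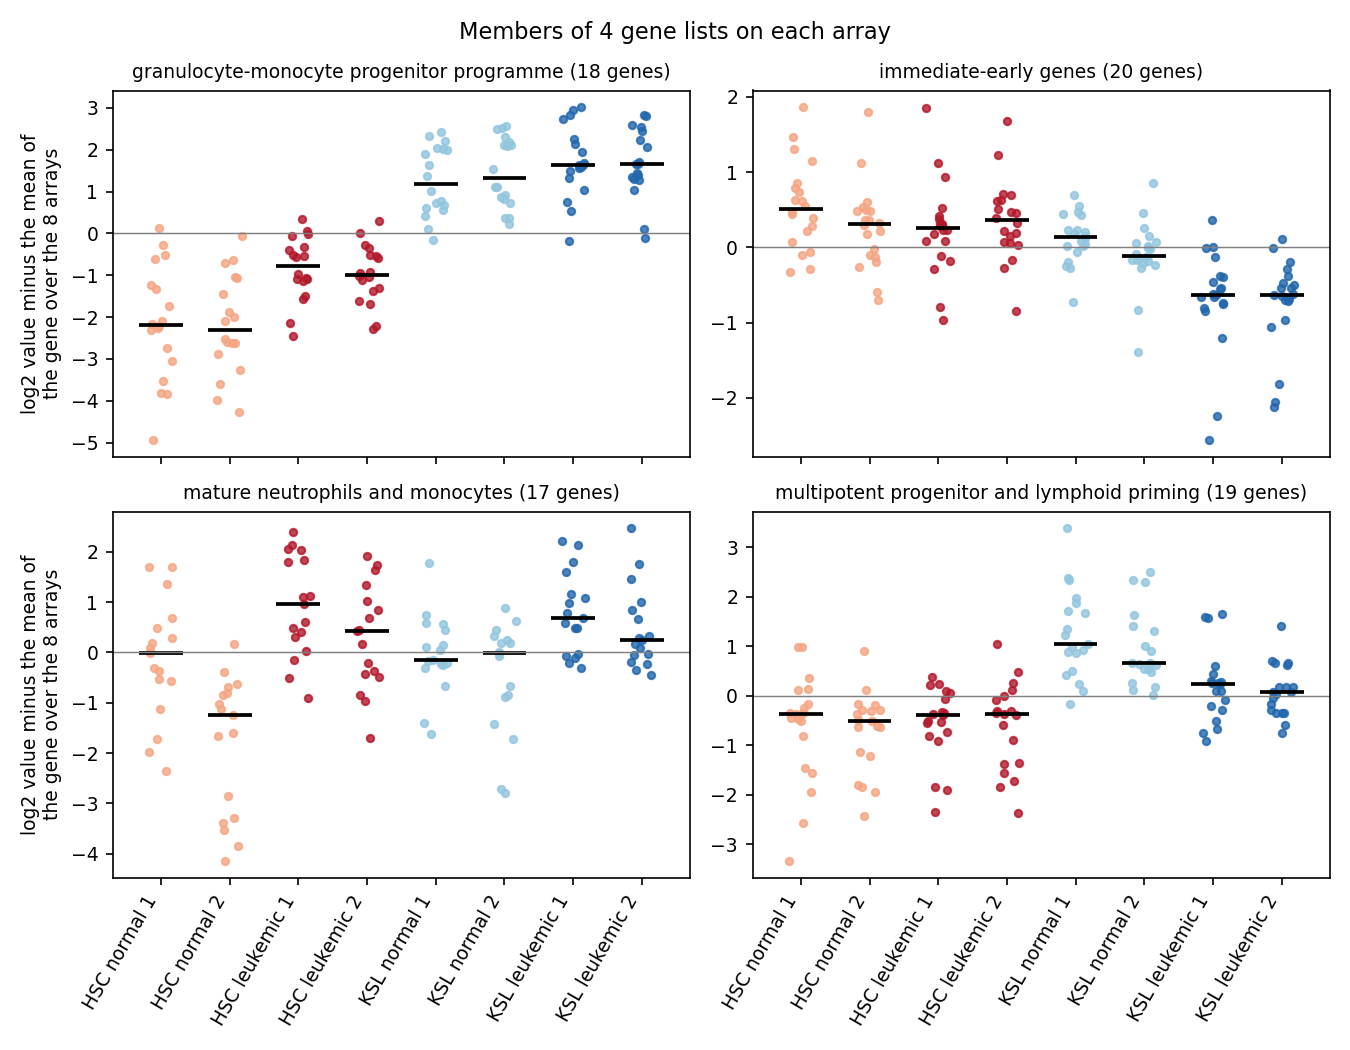
Log2 value of each member of 4 gene lists on each array, minus that gene's mean over the 8 arrays, with 1 point per gene and a black line at the median of the list. The granulocyte-monocyte list lay at -2.19 and -2.31 in HSC of normal mice and at -0.77 and -0.99 in HSC of leukemic mice, and the immediate-early list at 0.14 and -0.11 in KSL of normal mice and at -0.63 on both KSL arrays of leukemic mice.

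Gene by gene, 3 genes rose and 5 fell in KSL of leukemic mice, with 1446 at an unadjusted p under 0.05. The cytoplasmic tyrosine kinase gene Bmx rose by 1.78 ± 0.09 (adjusted p = 0.0426), Cirbp by 1.04 ± 0.04 (0.0322) and R3hcc1 by 0.71 ± 0.04 (0.0446). The platelet and endothelial matrix gene Mmrn1 fell by 1.56 ± 0.08 (0.0426), although another of its probe sets gave 0.00. The homeobox gene Six5 fell by 1.38 ± 0.06 (0.0322), and the endoplasmic reticulum chaperone gene Dnajb9 by 0.73 ± 0.04 (0.0453). Il12a, above, was the fourth, and the fifth was an immunoglobulin kappa variable segment, singled out after its values were seen. Next in rank without passing came the choline transporter family gene Slc44a4 at 0.78 ± 0.06 (0.0993), lactoperoxidase (Lpo) at 1.82 ± 0.14 (0.0993) and the adhesion receptor gene Adgrg1 at -1.31 ± 0.09 (0.096). The gate genes did not pass, with Slamf1 at -0.79 ± 0.51 (0.919), Cd48 at -0.13 ± 0.82 (1), Kit at -0.28 ± 0.37 (1) and Ptprc at -0.24 ± 0.21 (0.994).

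Each of the 8 arrays decided gene calls in KSL. Limma passed 6 genes without KSL normal 1 (1 of the 8, Mmrn1) and 5 without KSL normal 2 (0 of the 8). It passed 0 without KSL leukemic 1 (863 at an unadjusted p under 0.05), KSL leukemic 2 (1036), either HSC normal array (1799) or either HSC leukemic array (1956), and 0 with the male term (1587) or without the male arrays (1810). A shift to a common median gave 0 higher and 1 lower, and array weights 49 higher and 76 lower. With only the 4 KSL arrays in the fit limma passed 0 (3044).

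The average of both cell types, 4 arrays against 4, gave the mean leukemic difference of HSC and KSL, which a change in 1 of them alone can carry. Of the 15 genes that passed, 3 rose and 12 fell (2301 at an unadjusted p under 0.05), or 4 and 8 after quantile normalization. Cirbp rose by 0.88 ± 0.03 (adjusted p = 0.0122) and Atp8b4 by 0.99 ± 0.06 (0.046). Mmrn1 fell by 1.11 ± 0.06, Creb3 by 1.05 ± 0.07, Six5 by 0.99 ± 0.04 and Trps1 by 0.90 ± 0.04. Uevld fell by 0.80 ± 0.05, Pdrg1 by 0.72 ± 0.04, Il12a by 0.65 ± 0.04, Dnajb9 by 0.49 ± 0.03 and Dusp1 by 0.47 ± 0.03, with adjusted p between 0.0304 and 0.0493. The difference in Il12a was -0.14 in HSC and -1.16 in KSL. Among list members that did not pass over all genes, Socs3 rose by 1.41 ± 0.11 (adjusted p = 0.0583, and 0.00225 over the list alone). The gate genes did not pass, with Slamf1 at -0.78 ± 0.36, Cd48 at -0.06 ± 0.58, Kit at -0.09 ± 0.26 and Ptprc at -0.12 ± 0.15. Across the 15489 genes never at the floor, the fold changes in HSC and KSL, which share no arrays, correlated with r = 0.171 (Spearman rho 0.141). They may still not be independent. Replicate 1 of both normal groups had the male pattern, and the labels do not say whether HSC and KSL came from the same mice. Limma passed 83 genes without HSC normal 1, 21 without HSC normal 2, 106 without HSC leukemic 1, 144 without HSC leukemic 2 and 8 without KSL normal 2. It passed 0 without KSL normal 1 (1903 at an unadjusted p under 0.05), KSL leukemic 1 (1605) or KSL leukemic 2 (1639), with the male term (2058) and without the male arrays (2591). It passed 0 with arrays shifted to a common median (2292), 5 with array weights and 27 with the intensity trend and robust moderation.

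Of the lists, 10 were called in the average, and adjusted p was at least 0.113 with an estimated correlation for each. The granulocyte-monocyte progenitor list had a median of 0.82 with 17 of 18 higher (camera adjusted p = 3.01e-08). Adjusted over the list alone 6 rose, with Hp at 1.79 ± 0.20 (adjusted p = 0.0935 over all genes) and Ctsg at 1.59 ± 0.18 (0.0953). The mature neutrophil list had a median of 1.23 (3.01e-05; 0.61 without HSC normal 2), with Wfdc21 at 2.51 ± 0.38 (0.143) and Ccr2 at 2.01 ± 0.39 (0.187). The mast cell list had a median of 0.62 (0.000545; 0.96 without HSC leukemic 1), with Cma1 at 1.67 ± 0.16 (0.0802) and Fcer1a at 2.15 ± 0.46 (0.202). Lower were immediate-early genes with a median of -0.39 (1.35e-07) and multipotent progenitor genes with -0.52 (2.08e-05), whose medians were 0.09 and -0.04 in HSC and -0.68 and -1.08 in KSL. Also lower were long-term HSC identity with -0.39 (0.000257), leukaemic stem cell genes with -0.29 (0.000312) and the interferon response with -0.33 (0.000539). Erythroid genes had a median of -0.68 (0.00738), with Car2 at -1.16 ± 0.16 (0.131) and Gata1 at -1.14 ± 0.22 (0.188). They lost the call without HSC normal 1 (-0.30, 0.244), HSC leukemic 1 (0.0524), HSC leukemic 2 (0.0517) or the male arrays (-0.00, 0.432), and with the male term (0.243). Their median was -1.02 without HSC normal 2 and -0.42 without KSL normal 1. Heat shock and unfolded protein response genes had a median of -0.15 (0.0296) and lost the call without HSC normal 1 (0.0668), HSC normal 2 (0.064), HSC leukemic 1 (0.11), HSC leukemic 2 (0.177), KSL normal 1 (0.0578) or the male arrays (0.0641). It was lost as well without genes at the floor on any array (0.511), which leaves out Hspa1a and Hspa1b, without the lowest 40% of genes (0.153) and with the male term (0.0869).

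The interaction asked whether the leukemic difference in HSC was larger or smaller than in KSL, and 4 of the lists it called kept the call whichever array was left out. Immediate-early genes had a median difference of 0.76 (camera adjusted p = 5.26e-07, and adjusted p = 0.175 with an estimated correlation). Over the list alone 9 passed, among them Egr1 at 1.56 and Fosb at 1.16. Multipotent progenitor genes had a median of 1.01 (2.03e-06, and adjusted p = 0.175 with an estimated correlation), with Dntt at 2.41 and Ccr9 at 0.99 among 6 that passed over the list alone. Megakaryocyte genes had a median of 1.22 (0.000444, and adjusted p = 0.302 with an estimated correlation), or 0.80 without HSC normal 1, with Mmrn1 at 0.91 passing over the list alone. Glycolysis genes had a median of -0.37 (0.00219, and adjusted p = 0.175 with an estimated correlation). The mitophagy receptor gene Bnip3, at -1.31, and the oxygen-sensing hydroxylase gene Egln3, at -2.06, passed over the list alone. In these lists limma passed 0 members over all genes, with 10, 7, 6 and 5 at an unadjusted p under 0.05.

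Gene by gene, 1 of 18193 genes passed (1653 at an unadjusted p under 0.05), Slc16a12 (adjusted p = 0.0245). It was at 4.47 in HSC of normal mice and at the floor in the other 3 groups, so its difference in KSL was not measured and the call rests on the floor. Il1r1 was at 2.29 ± 0.12 and R3hcc1 at -1.09 ± 0.06 (both adjusted p = 0.0578), with Fosl2 at 1.47 ± 0.09 (0.0894). Bmp4 and Mmp13, at or near the floor in KSL, and Bmx, at or near it in HSC, ranked high as well, but their differences between the cell types were not measured for the same reason. Il12a was at 1.01 ± 0.08 (0.166) and the epidermal envelope gene Lor at 0.63 ± 0.05 (0.151). Limma passed 32 genes without HSC normal 1, 9 without HSC normal 2, 51 without HSC leukemic 1, 68 without HSC leukemic 2 and 3 without KSL normal 2. It passed 0 without KSL normal 1 (1517 at an unadjusted p under 0.05), KSL leukemic 1 (1088) or KSL leukemic 2 (1296), and 0 with the male term (1744) or without the male arrays (2218).

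The last comparison set HSC against KSL in normal mice, which differed in the CD150+ CD48- gate and in control probes. The 3 prime minus 5 prime difference was -2.04 and -1.74 in HSC against -1.28 and -1.58 in KSL for Tfrc and -0.37 and -0.38 against -0.48 and -0.48 for Actb, and overlapped for Gapdh (0.78 and 0.83 against 0.89 and 0.74). The hybridisation spike-in BioB was at 9.40 and 9.48 in KSL and at 9.84 or more in HSC, and BioC was at 12.19 and 11.97 in HSC against 11.43 and 11.56 in KSL.

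Genes of long-term HSC identity were higher in HSC for 23 of 23 members, with a median of 2.56 (camera adjusted p = 3.73e-20, and 0.0142 with an estimated correlation). Of these, 22 passed over the list alone and 7 over all genes. The homeobox gene Hoxb5, a marker of long-term HSC, was higher by 3.63 ± 0.35, Procr by 3.25 ± 0.29, the elongation cofactor gene Mllt3 by 3.22 ± 0.23 and the zinc finger gene Mecom by 2.82 ± 0.35. Granulocyte-monocyte progenitor genes were lower for 18 of 18 members, with a median of -3.70 (8.94e-21, and 0.0142 with an estimated correlation), with 16 passing over the list alone and 8 over all genes. Ctsg was at -6.49 ± 0.25, neutrophil elastase (Elane) at -6.13 ± 0.77, Ly86 at -6.03 ± 0.38 and Ms4a3 at -5.32 ± 0.20. The mast cell list had a median of -3.77 (3.02e-09, and 0.0301 with an estimated correlation), with the eosinophil granule gene Prg2 at -5.78 ± 0.32 and the IgE receptor beta chain gene Ms4a2 at -4.06 ± 0.27. Multipotent progenitor genes had a median of -1.40 (1.15e-12, and 0.0267), with Dntt at -4.60 ± 0.42, Il7r at -4.02 ± 0.32, Cd52 at -2.35 ± 0.22 and Cd53 at -2.33 ± 0.28. T and NK genes had a median of -1.69 (6.56e-05, and 0.0447), with Cd3e at -3.25 ± 0.20 and Nkg7 at -2.48 ± 0.25. Proliferation genes had a median of -0.64 (5.56e-09, and 0.0207), with Bub1 at -1.26 ± 0.13, Kif11 at -1.09 ± 0.07 and topoisomerase 2 alpha (Top2a) at -0.97 ± 0.05. Of the gate genes, Slamf1 was at 2.72 ± 0.51 (adjusted p = 0.0958), Cd48 at -3.26 ± 0.82 (0.158), Kit at 0.62 ± 0.37 (0.514) and Ptprc at -0.39 ± 0.21 (0.467).

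A further 9 lists were called between HSC and KSL of normal mice, and their calls were lost with an estimated correlation. Megakaryocyte genes had a median of 1.07 (camera adjusted p = 3.11e-06, and adjusted p = 0.248 with an estimated correlation; 0.64 without HSC normal 2). Mmrn1 was higher by 3.65 ± 0.08, Rab27b by 2.49 ± 0.30 and Nfe2 by 1.05 ± 0.14. Interferon response genes had a median of 0.51 (0.00384, and adjusted p = 0.0859 with an estimated correlation), with Oasl2 higher (adjusted p = 0.023). Immediate-early genes had a median of 0.30 (0.00906, and adjusted p = 0.299 with an estimated correlation; call lost without HSC normal 1, 0.228, and with the normal arrays alone, 0.0502; 0.18 without KSL normal 2). Nr4a2 was at 2.69 ± 0.29 and Dusp1 at 0.47 ± 0.04. Leukaemic stem cell genes had a median of 0.31 (0.0253, and adjusted p = 0.145 with an estimated correlation). Mycn was at 2.10 ± 0.10, Meis1 at 1.35 ± 0.16 and Erg at 0.93 ± 0.09. The median was 0.62 without HSC normal 2 and 0.20 without KSL normal 2, and there was no call without HSC normal 1 (0.07, 0.245), without both male arrays (0.09, 0.275), with the male term (0.0556) or with the normal arrays alone (0.0529).

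Oxidative phosphorylation, lower in HSC, had a median of -0.16 (0.00384, and adjusted p = 0.299 with an estimated correlation; call lost without HSC normal 2, 0.0627, and without the lowest 40% of genes, 0.0784), with the cytochrome c gene Cycs at -0.76 ± 0.09. B lineage genes had a median of -0.53 (0.0109, and adjusted p = 0.133 with an estimated correlation; -0.31 without HSC normal 1 and -0.34 without KSL normal 2; call lost with the normal arrays alone, 0.0529). Cd79b was at -1.17 ± 0.18 (0.0677 over all genes) and Blnk at -1.44 ± 0.29 (0.111). Mature neutrophil markers had a median of -0.80 (0.0429, and adjusted p = 0.518 with an estimated correlation). It was 0.31 without HSC normal 2 (0.878), -0.47 without KSL normal 1 (0.126) and -1.67 without HSC normal 1. The call was also lost with the male term (0.102), without the lowest 40% of genes (0.141), after quantile normalization (0.0507) or cyclic loess (0.0514), and with the normal arrays alone (0.0504). Ccr2 was at -3.63 ± 0.56 (0.0652). Erythroid genes had a median of 0.68 (0.0477, and adjusted p = 0.463 with an estimated correlation), with Epor at 1.81 ± 0.29 (0.0695), and of 1.36 without HSC normal 2. They lost the call without HSC normal 1 (0.12, 0.956), KSL normal 2 (0.45, 0.154), either HSC leukemic array (0.0805) or either KSL leukemic array (0.0567). The same held without both male arrays (0.33, 0.371), with array weights (0.0612), every probe set (0.074) and the normal arrays alone (0.111). TNF and NF-kB genes had a median of -0.00 and a mean of -0.57 (0.0453, and adjusted p = 0.299 with an estimated correlation). Their median was -0.13 without KSL normal 2 and -0.27 without both male arrays. Ccl5 was at -3.23 ± 0.53 (0.0749) and Tnf at -1.10 ± 0.19 (0.0806). The list lost the call without HSC normal 1 (0.0526), HSC normal 2 (0.0747), KSL normal 1 (0.0731), either HSC leukemic array (0.059) or both male arrays (0.0617). It also lost it after quantile normalization (0.0507) or cyclic loess (0.0514), without the lowest 40% of genes (0.02, 0.17), with every probe set (0.179) or their mean (0.0688), and with the normal arrays alone (0.0699).

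**Figure D3:**
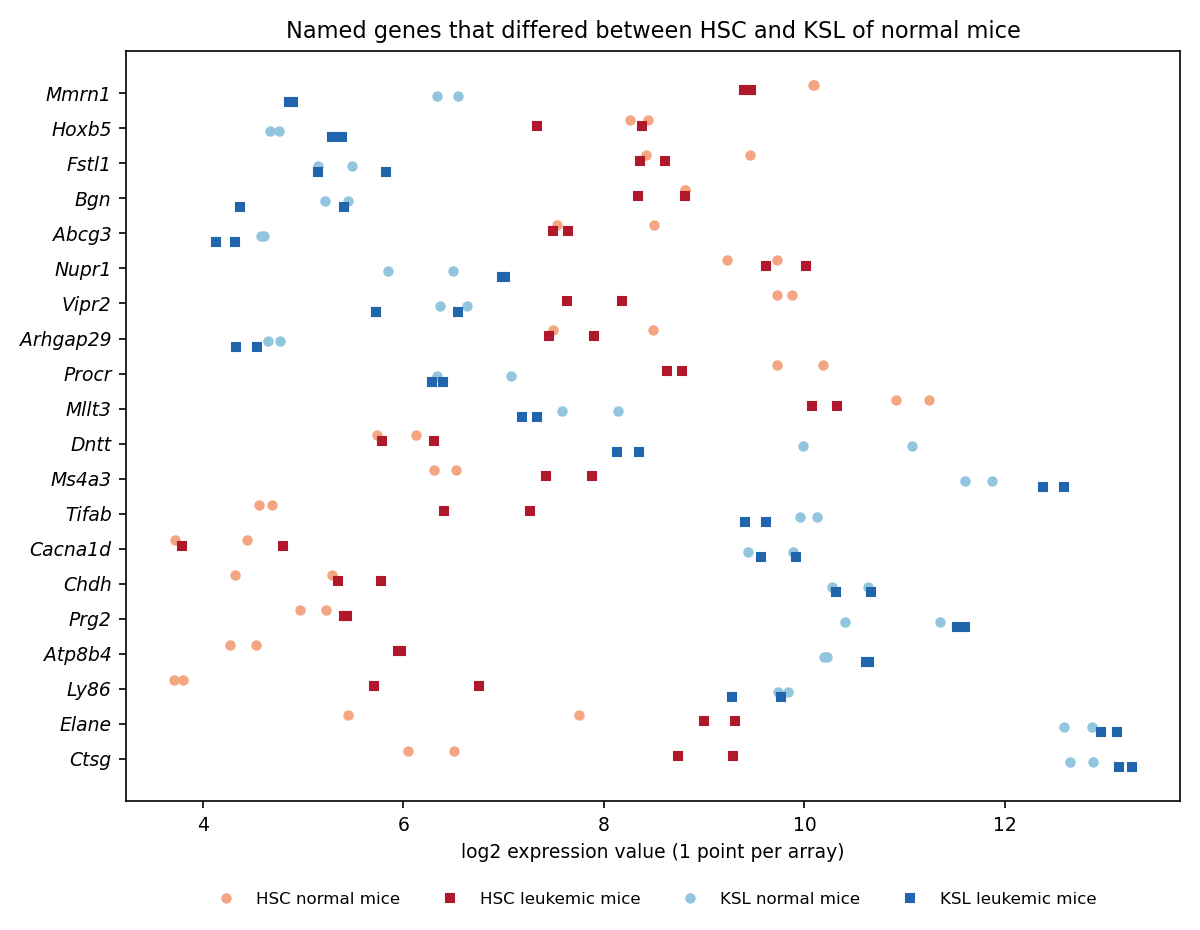
Log2 expression value on each array, 1 point per array, of the 20 named genes with the largest differences between HSC and KSL of normal mice, by group. Ctsg lay at a mean of 6.27 in HSC and 12.76 in KSL of normal mice, and Hoxb5 at 8.35 and 4.72.

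In all, 146 genes were higher and 182 lower in HSC than in KSL of normal mice (2951 at an unadjusted p under 0.05). Beyond the list members, the higher genes included the secreted glycoprotein gene Fstl1 at 3.63 ± 0.43, the proteoglycan gene Bgn at 3.48 ± 0.38, and Abcg3 at 3.42 ± 0.33. They also included the stress-induced regulator gene Nupr1 at 3.30 ± 0.30, Vipr2, a receptor for vasoactive intestinal peptide, at 3.30 ± 0.34, and Arhgap29 at 3.28 ± 0.36. The lower genes included Atp8b4 at -5.81 ± 0.09 (adjusted p = 0.00065), the choline dehydrogenase gene Chdh at -5.65 ± 0.39 and Tifab at -5.42 ± 0.30. The calcium channel gene Cacna1d was at -5.58 ± 0.45, where another probe set gave -0.08. Among lists that were not called, IL-6 and JAK-STAT3 genes had a median of 0.09 (camera adjusted p = 0.165), with Lifr at -0.64 ± 0.11 (0.0789) and Cebpd at -1.17 ± 0.20 (0.0801). Limma passed 460 genes without HSC normal 1 (148 of the 328 among them), 292 without HSC normal 2 (119), and 463 without either HSC leukemic array (236). It passed 48 without KSL normal 1 (32), 42 without KSL normal 2 (29) and 20 without either KSL leukemic array (19). With the male term 76 were higher and 92 lower, and without the male arrays 1 and 3. With only the 4 arrays of normal mice in the fit limma passed 0 (2916 at an unadjusted p under 0.05).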

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

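The tests on mature neutrophils, on antibody-secreting cells and on handling below, and the 2 later forms of the test on the KSL gate, were chosen after results were seen, and the others were written before.

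A test of the difference itself flagged 12 lists and 1 gene for a leukemic difference that was not the same in HSC and in KSL. For each list, camera's adjusted p was under 0.05 with the preset correlation and at least 0.175 with an estimated one. The lists that kept the flag whichever array was left out were immediate-early genes (median difference 0.76), multipotent progenitor and lymphoid priming (1.01), megakaryocyte lineage and platelets (1.22, or 0.80 without HSC normal 1; not called with fry, 0.109) and glycolysis and hypoxia response (-0.37). The T and NK lineage had 0.83 (not called without HSC leukemic 2, adjusted p = 0.139; or without the lowest 40% of genes, 0.177; 0.49 without KSL normal 2). The granulocyte-monocyte progenitor programme had 0.51 (not called without HSC leukemic 1, 0.101, or KSL normal 2, 0.0613; 0.96 without HSC normal 1, 0.77 without HSC leukemic 2 and 0.97 without the male arrays). The B lineage had 0.50 (not called without HSC leukemic 1, 0.0511), and quiescence and cell cycle inhibitors 0.35 (not called without HSC leukemic 1, 0.176, or HSC normal 2, 0.0828). TNF and NF-kB genes had 0.46, IL-6 and JAK-STAT3 signalling 0.44, homing and niche adhesion 0.24 and leukaemic stem cell genes 0.22, and each of these lost its call on leaving out any 1 of at least 4 arrays and with fry. The TNF median was 0.73 without HSC normal 1 and 0.71 without the male arrays, the homing median 0.58 without HSC leukemic 2 and 0.38 without KSL normal 2, and the leukaemic stem cell median 0.39 without HSC normal 1. The TNF, homing and leukaemic stem cell lists also lost the call with every probe set tested (0.107) or probe sets averaged (0.0646, 0.0646 and 0.235). Homing lost it with the male term (0.111), homing and IL-6 without the male arrays (0.308 and 0.278), and leukaemic stem cell genes with array weights (0.0639) or without genes at the floor on all (0.0566) or any arrays (0.0514). The gene was Slc16a12, at -1.15, but KSL of both groups and HSC of leukemic mice were at the floor, so its difference in KSL was not measured and this value is set by the floor.

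The higher granulocyte-monocyte progenitor genes in HSC of leukemic mice were weighed first. Leaving out 1 normal HSC array left the median at 1.09 or above, which argues against a single normal array as the cause. It does not exclude it, because HSC of normal mice then rests on 1 array. The form written in advance took genes at least 4-fold higher in KSL of leukemic mice than in HSC of normal mice, matched to the members on that gap. They had a median of 1.15 against 1.43 for 15 list members (0.447 without matching). The matched value is over 50% of the members, as predicted for cells of the wider KSL gate. In this form, however, gap and fold change share the normal arrays. In a later form, with the gap taken against all 4 HSC arrays, matched genes had 0.58, with 13 of 15 members above them. With the gap taken against 1 normal array and the fold change against the other, matched genes had 0.57 against 1.66 (13 of 15 above) and 0.24 against 1.24 (12 of 15). These medians are under 50% of the members, but the upper quartiles of 1.30 and 1.19 pass that bound. The forms thus disagree, and cells of the wider KSL gate cannot be told apart from expression by the HSC. The mature neutrophil list stayed 0.48 above the nearer normal array, so mature cells in the sort cannot be told apart either, and single-cell data or a second sort would be needed.

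Immunoglobulin transcripts were weighed next, and were picked after their values were seen. For Igha and Jchain, HSC of normal mice was the low group. Igha was at 6.81 and 7.67 there against 12.01 and 12.94 in HSC of leukemic mice (adjusted p = 0.0933). It was at 12.67 and 13.83 in KSL of normal mice and 13.02 and 13.21 in KSL of leukemic mice. In the same order of groups Jchain was at 8.08 and 4.50, 10.03 and 10.57 (0.276), 11.33 and 11.97, and 10.72 and 11.02. Not every immunoglobulin transcript had this pattern. Ighg3 was low in HSC of both normal (4.56 and 4.42) and leukemic mice (4.91 and 5.07), against 7.75 and 10.59 in KSL of normal mice. The kappa segment called in KSL was at 4.89 and 4.69, 4.88 and 4.96, and 11.20 and 11.31 in these groups. Igk was at 11.14 on HSC normal 1 and 4.42 on HSC normal 2, against 13.23 and 13.51 in HSC of leukemic mice. The 15 markers of antibody-secreting cells that are not immunoglobulin genes, Jchain included, had a median of -0.31 in KSL and of 0.33 in HSC, under the bound of 0.5 set for excluding such cells, but their HSC quartiles of 0.02 and 1.07 span it, and a rule on the spread applied after the value was seen left the result open. Without Jchain the median of the other 14 was 0.26 (quartiles 0.00 and 0.89), and 5 of 14 had both leukemic arrays above both normal arrays where chance gives 16.7%. Antibody-secreting cells, or their RNA, and transcription in the sorted cells cannot be told apart here.

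The lower immediate-early and lymphoid-priming genes in KSL of leukemic mice were weighed last. Without the male arrays the immediate-early median was -0.60 and the progenitor median -0.96, which keeps 88.7% and 88.8% of the medians with all arrays. This argues against the male pattern as the main source. It does not exclude it, because KSL of normal mice then rests on 1 array. On that array, KSL normal 2, the Y-linked Kdm5d was still at 5.86, against 4.68 and 3.65 in KSL of leukemic mice. Hspa1a at -5.36, Hspa1b at -6.18 and Cirbp at 1.04 (adjusted p = 0.0322) in KSL, the first a lower bound in size, were seen before and prompted a further test. These values go with a temperature difference before lysis. In KSL, however, 15 other heat-inducible genes had a median of 0.18 with quartiles of -0.13 and 0.37, which argues against it there. In HSC 11 of these 15 were lower, with a median of -0.16, so it stays open for HSC. The part of the prediction on a cold-inducible gene was not tested. The immediate-early median in HSC was 0.0888. The labels do not say that HSC and KSL came from the same mice. Handling before lysis thus cannot be told apart from a change in the mice, and a response of KSL to the leukemic marrow stays open. Whether such a response would lie within cells or in the mix of cells of the gate was not tested.

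The genes called in the average were set against every other split of the arrays into 4 and 4. Of 34 splits that could be fitted, the real one included, 15 called as many as the real 15, the highest other split calling 52, so the count of calls by itself does not exclude chance. At an unadjusted p under 0.05 the real split had 2301 genes and the highest other split 1884. Among the 18 splits with 2 arrays of each cell type on each side the highest other split called 2, where the smallest share that can be reached is 0.0556, and 13 of the 16 unbalanced splits called more than the real one. A first version with an additive fit, replaced after it was seen, called 0 genes for the real split, with 1934 at an unadjusted p under 0.05 against 1366 for the highest other split.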

How the results depend on the processing

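No named gene that passed changed sign in these settings, although a further probe set of Rnf217 gave -0.30 and one of Lpgat1 -0.85, and camera's direction for a called list changed in no setting. In HSC against KSL, however, the median of the mature neutrophil list turned from -0.80 to 0.31 without HSC normal 2 (adjusted p = 0.878), and that of TNF and NF-kB genes from -0.00 to 0.02 without the lowest 40% of genes (adjusted p = 0.17). Leaving out genes at the floor, the male term and leaving out the male arrays were chosen after seeing the data. Counts of genes that passed in limma are given as higher and lower, for leukemic against normal mice in HSC (11 and 7 as reported), in KSL (3 and 5), in the average (3 and 12) and in the interaction (0 and 1), and for HSC against KSL in normal mice (146 and 182). With the deposited values quantile-normalized again, the counts were 6 and 6 in HSC, 2 and 4 in KSL, 4 and 8 in the average, 0 and 2 in the interaction, and 130 and 177 in HSC against KSL. Cyclic loess gave 8 and 5, 2 and 4, 2 and 6, 0 and 0, and 139 and 193. Arrays shifted to a common median gave 16 and 4, 0 and 1, 0 and 0, 0 and 0, and 214 and 305, and 9 of the 20 calls in HSC were among the 18 as reported. The mean of the probe sets of a gene gave 7 and 4, 3 and 4, 5 and 11, 3 and 4, and 212 and 266, and every probe set tested 14 and 17, 2 and 3, 3 and 11, 0 and 2, and 172 and 223. The intensity trend with robust moderation gave 12 and 7, 3 and 5, 9 and 18, 1 and 4, and 143 and 176. Array weights gave 0 and 2, 49 and 76, 1 and 4, 0 and 1, and 89 and 130, with weights that favour the less variable KSL arrays. For these settings the cause was not tested.

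Settings that test fewer genes or other thresholds moved the counts as well. Leaving out the lowest 40% of genes gave 11 and 1, 1 and 1, 0 and 0, 2 and 0, and 241 and 272. Without genes at the floor on all arrays they were 15 and 5, 0 and 1, 0 and 0, 0 and 0, and 233 and 292, and without genes at the floor on any array 13 and 4, 1 and 1, 0 and 0, 0 and 0, and 257 and 289. With these filters most calls in HSC were other genes than the 18 as reported. Of the calls in HSC, 2 of 12 were shared with the 18 without the lowest 40% of genes. The shared calls were 9 of 20 without genes at the floor on all arrays and 6 of 17 without those on any array. An adjusted p under 0.10 gave 51 and 47, 6 and 11, 38 and 45, 3 and 3, and 378 and 411, and a log2 fold change of at least 1 as well 8 and 6, 2 and 4, 0 and 4, 0 and 1, and 100 and 147. With only the arrays of the groups compared, which leaves 2 residual degrees of freedom, limma passed 0 and 0 in HSC (1459 at an unadjusted p under 0.05), 0 and 0 in KSL (3044) and 0 and 0 in HSC against KSL (2916), and the average and the interaction, which use all groups, have no such fit. The male term gave 0 and 0 in the first 4 comparisons and 76 and 92 in HSC against KSL, and leaving out the male arrays 0 and 0 in the first 4 and 1 and 3. Unadjusted p was under 0.05 for 1567 genes or more in the average wherever limma passed 0 in these settings, and for 1225 or more in the interaction.

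With each of the 8 arrays left out in turn, counts ranged from 0 to 170 higher and 0 to 92 lower in HSC, 0 to 1 and 0 to 6 in KSL, 0 to 84 and 0 to 60 in the average, 0 to 50 and 0 to 29 in the interaction, and 5 to 248 and 15 to 249 in HSC against KSL. The lone sample of a group is then assumed to vary like the other groups. Without an HSC array the pooled spread rests more on the KSL arrays, whose replicates differ less.

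With the replicate block, limma passed 0 and 0 in HSC (2433 at an unadjusted p under 0.05), 0 and 0 in KSL (1436), 0 and 0 in the average (2255), 0 and 0 in the interaction (1662), and 7 and 12 in HSC against KSL. The labels do not pair the samples by number, although replicate 1 of both normal groups had the male pattern and replicate 2 a female level of Xist. Within the normal groups the block therefore also carries that difference. The correlations between groups of the replicate differences, across 15489 genes, were 0.0011, 0.0817, -0.0015, 0.0856, -0.0076 and -0.0421.

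Of 57 list calls, all 57 were kept under the common median and the intensity trend, 55 under quantile normalization, 53 under cyclic loess, 48 without the lowest 40% of genes, 54 with array weights, 55 with the replicate block, 53 with the mean of probe sets and 52 with every probe set. The male term kept 49, leaving out the male arrays 46, fry 36, and camera with an estimated correlation 6. Whichever array was left out, calls were kept for 1 of 5 lists in HSC, 13 of 15 in KSL, 8 of 10 in the average, 4 of 12 in the interaction and 9 of 15 in HSC against KSL. Of the 75 results for named genes that passed, 62 stayed past the threshold under quantile normalization, 47 under the common median, 21 with the male term and 2 without the male arrays. With array weights 43 stayed, without either KSL leukemic array 5, 9 without KSL normal 1, 8 without KSL normal 2, and with the replicate block 4. With only the arrays of the groups compared 0 of 63 stayed in limma (unadjusted counts above). Signal at the floor, on 14.9% to 15.8% of probe sets per array, limits what can be said of dim genes.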

Other observations

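The temperature test below was written before its genes were looked at, prompted by 3 genes already seen, and the immunoglobulin segments were picked after their values were seen.

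Transcripts of the inducible Hsp70 chaperones were at or near the floor in leukemic mice. Hspa1a, which encodes an Hsp70 protein made under heat and other proteotoxic stress, was at 6.25 and 5.86 in HSC and 9.76 and 7.60 in KSL of normal mice, and at the floor on all 4 arrays of leukemic mice. Hspa1b, its neighbouring paralogue, was at 8.53 and 6.76 in HSC and 11.29 and 9.18 in KSL of normal mice, at the floor on both HSC arrays of leukemic mice, and at 4.31 and 3.80 in KSL. Adjusted over the heat shock and unfolded protein response list alone, both fell in the average (adjusted p = 0.00411 for each), at -4.05 and -5.25, whose size is a lower bound because of the floor, and over all genes limma gave 0.11 and 0.109. Cirbp, which encodes an RNA-binding protein induced by mild cold, was at 10.47 and 10.46 in HSC of normal mice against 11.15 and 11.22, and at 9.96 and 9.97 in KSL against 10.98 and 11.03. Other heat-inducible genes differed less, with Dnaja1 at -0.99 in HSC and -0.26 in KSL, Chordc1 at -0.76 and -0.46, and Cacybp at 0.42 in KSL, and 11 of 15 were lower in HSC and 5 of 15 in KSL (median -0.16 and 0.18).

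Immunoglobulin variable segments differed from one another in HSC. Of 16 measured, 5 were at the floor on both HSC arrays of normal mice, and 1 of these was more than 2 log2 units above the floor on both HSC arrays of leukemic mice. The lambda segment Iglv1 was at 4.07 and 5.15 in HSC of normal mice and at 11.03 and 10.86 in HSC of leukemic mice (adjusted p = 0.133), and the kappa segment Igk-V21 at 3.61 and 3.67 against 11.84 and 11.04 (0.0531).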
